A study of Mus musculus with 12 samples.

How the data were processed

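Bulk RNA sequencing covered 12 subcutaneous 4T1 tumours, 3 in each of 4 groups, each from a different female BALB/c mouse. Per the labels, mice were acclimatized for 3 days before inoculation, IOX2 injections of 10 mg/kg began on day 9 after inoculation and were repeated each day, 10 days in all, vehicle was given to the control groups, and tumours were collected on study day 22. The study as a whole used 24 mice. Libraries were read as pairs of 150 bases.

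Per the submitters' processing notes, the tools were fastp 0.20.1, HISAT2 2.1.0, HTSeq 0.11.2, DESeq2 1.22.2 and R 3.5.1, with the mouse build GRCm39. The notes list the tools without saying what each was used for; by their usual use, reads were trimmed with fastp, aligned with HISAT2 and counted per gene with HTSeq. The gene annotation and the strandedness are not given in the sources used here. The deposited count table holds raw whole-number counts for 35434 genes, of which 24312 had any count. The deposited FPKM table holds the authors' values for the same 35434 genes. Checked against the counts, the gene length that each FPKM value above 0 implies was a whole number within 0.01 base for 100% of values, so those values are fragments scaled by gene length and by the library total over all genes. The reference at hand was an older mouse build (GRCm38), so no gene positions are given. It was used only for the GC content of genes, matched by name for 94.2% of the genes tested.

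Library totals ran from 31661685 counts (HC1) to 40019343 counts (MI2). The other totals were 38939996, 39590774 and 39613623 counts in MC1 to MC3, 38791094 in MI1, 37913875 in MI3, 39444390 and 39235886 in HC2 and HC3, and 39501804, 39762631 and 39492244 in HI1 to HI3. A floor of 3 counts, the most that a count of 0 allows, equals 0.0750 to 0.0948 CPM (a gene's counts scaled to library size in the standard unit of edgeR) per library, and it covers counting error only. The 20 most abundant genes took 8.19% to 8.90% of the counts, and mitochondrial genes 1.61% to 2.96%. TMM factors ran from 0.925 to 1.03.

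Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, the filterByExpr filter (15269 genes kept), and a quasi-likelihood fit of all 12 libraries with 1 mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Adjusted p values of genes come from edgeR unless another tool is named, and each is followed by the log2 change with its standard error (SE) or group values. The 7 comparisons were altitude with vehicle (HC against MC), altitude with IOX2 (HI against MI), IOX2 at ambient altitude (MI against MC), IOX2 at simulated altitude (HI against HC), the altitude by IOX2 interaction, and the altitude and IOX2 effects each averaged over the other factor. An exact test of 3 mice against 3 cannot give a p below 0.1, which is why the fit shares its spread estimates across genes. Expression values are TMM-scaled CPM, as mean ± SD over 3 mice.

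Lists of pathway and cell-type genes, 48 in number with 810 members, were written from general knowledge. The table held 805 of the members, and 778 passed the filter. A list needed at least 4 tested members, which 46 lists had. Lists were tested against all other genes with camera of limma 3.58.1 at its preset correlation of 0.01, and again with the correlation between genes estimated from the data. Camera p values are adjusted over the 46 lists. The direction of each list's genes alone was tested with fry. Members were also adjusted over the list alone. Per-library list scores are the mean over members of log2 CPM (prior count 2) minus each gene's mean over the 12 libraries. The genes Mx1, Mx2, Ighm, Ighg1 and Igkc were not found under these names and are not analysed here.

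Genes named in the text follow a rule. The genes Egln1, Egln2, Egln3, Hif1a, Epas1, Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Hmox1, Ptgs2 and Slc40a1 are always named. In each comparison of 2 groups, the 6 largest rises and 6 largest falls are named among called genes with a mean of at least 5 CPM in the higher group and groups that do not overlap. In the interaction and the averages, the 5 genes with the smallest adjusted p are named under the same conditions. Predicted genes, genes named after clones or accessions, pseudogenes and immunoglobulin or T-cell receptor segments are left out. Where fewer genes pass, those that pass are named, and where fewer than 3 pass, the 5 with the smallest p are named and said not to pass. For each list described, up to 4 members with the smallest adjusted p are named. Any other gene is said to have been chosen after its values were seen. An item that counts of calls include is not reported here by name.

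The comparisons, the lists, the rule for named genes and most alternative settings were fixed before the data were examined. The alternatives of that kind were DESeq2 1.42.0 (Wald test), edgeR with DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, limma-voom, a fit of only the 6 libraries compared, a block for the replicate number, limma on log2 of FPKM plus 1 or plus 0.1 (genes of at least 1 FPKM in 3 libraries), and leaving out each library in turn. A correction for GC content and gene length, a fit without both MI1 and MI3, and another version of the edgeR fit were added later.

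The procedure was tested on simulated data, with 200 changed genes in each of 5 simulations. Counts were drawn for each gene on its own, at its mean and spread and at the depths of the 12 libraries. Of genes changed 2-fold, 59.1% were called with altitude compared in vehicle mice only and 74.9% with altitude averaged over treatment. Of genes changed 1.5-fold, 25.1% and 52.8% were called. Calls on unchanged genes made up 6.01% and 5.32% of all calls. When the erythroid list was shifted, it was called and 0 of the other lists were. Simulated genes of a list did not move together, whereas in the real libraries they did (estimated correlation 0.898 for ribosomal genes in HC against MC). The simulations therefore do not show how often preset camera calls unchanged lists of correlated genes.

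Similarity of the altitude and IOX2 effects was measured as the covariance of their log2 changes across genes. Both effects share the MC libraries, so the covariance was compared with 100 simulations of libraries without effects. No library was left out of the main comparisons, and no sample column was left unmapped.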

Results

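Tumours of 4T1, a mouse triple-negative breast cancer line, were grown in mice that lived at ambient altitude, about 1500 m, or in a hypobaric chamber simulating 3500 m, where each breath carries less oxygen. The mice received vehicle or IOX2, an inhibitor of PHD2, the enzyme encoded by Egln1 that marks hypoxia-inducible factors (HIFs) for destruction while oxygen is plentiful. The groups are MC (ambient, vehicle), MI (ambient, IOX2), HC (simulated altitude, vehicle) and HI (simulated altitude, IOX2), with n = 3 mice each. As described, only HC and HI mice lived in the chamber, so effects of altitude and of chamber housing cannot be told apart. Altitude below stands for both. The questions were what altitude changes in the tumour, whether IOX2 changes the same genes, and whether genes of ferroptosis, an iron-dependent cell death through oxidized lipids, move with either.

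The oxygen sensors and the HIF subunits themselves did not pass the threshold of edgeR in any of the 7 comparisons. Egln1, the target of IOX2, was at 160.5 ± 11.7 CPM in MC, 160.6 ± 23.0 in MI, 161.5 ± 30.9 in HC and 214 ± 49.99 in HI (SD, n = 3). Egln2, a partner in oxygen sensing, was at 55.2 ± 7.10, 52.3 ± 5.11, 50.5 ± 2.04 and 50.9 ± 1.67 CPM in the same order. Egln3, itself a HIF target gene, was at 243 ± 41.9, 216 ± 32.2, 178 ± 58.6 and 192 ± 28.0 CPM. For Hif1a, which encodes the widely expressed HIF subunit, the means were 297 ± 38.1, 473 ± 232, 270.4 ± 38.9 and 278 ± 33.6 CPM, with 721 in library MI3. Epas1, which encodes the HIF subunit prominent in vessels, was at 33.6 ± 3.86, 42.0 ± 10.3, 46.7 ± 12.5 and 35.3 ± 5.66 CPM. As a list, oxygen-sensing genes were not called by preset camera in any comparison (adjusted p = 0.457 to 0.911). The list's adjusted p = 0.607 to 0.966 with an estimated correlation. Its median, mean and test differed in sign in 3 comparisons, HI against MI, MI against MC and the averaged IOX2 effect.

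None of the named genes of ferroptosis and iron handling passed the threshold in any comparison either. Slc7a11, which imports the cystine that protects cells from ferroptosis, had its lowest mean in HC: 51.0 ± 25.0 CPM in MC, 52.7 ± 22.4 in MI, 20.4 ± 6.12 in HC and 47.3 ± 0.942 in HI. Its log2 change at altitude with vehicle was -1.32 (SE 0.38, adjusted p = 0.249), and the groups did not overlap. Gpx4, the enzyme that repairs oxidized membrane lipids, was at 265 ± 36.4, 230.1 ± 20.1, 252 ± 14.9 and 237 ± 11.7 CPM. Acsl4, which loads membranes with oxidizable fatty acids, was at 501 ± 34.3, 673 ± 318, 450.1 ± 55.4 and 519 ± 62.9 CPM, with 1033 in MI3. The receptor for iron uptake, Tfrc, had higher means at altitude: 76.8 ± 18.9 CPM in MC and 104 ± 28.7 in MI, against 142 ± 2.57 in HC and 163 ± 74.0 in HI. Averaged over treatment, the log2 change of Tfrc was 0.77 (SE 0.21, adjusted p = 0.115). The iron exporter gene Slc40a1 had lower means there: 6.96 ± 2.35, 7.30 ± 1.05, 4.13 ± 0.139 and 4.30 ± 0.921 CPM, a log2 change of -0.76 (SE 0.18, adjusted p = 0.0779). Fth1, which encodes an iron-storing ferritin chain, was at 2276 ± 232, 2072 ± 158, 2349 ± 367 and 2886 ± 394 CPM. The heme-degrading enzyme gene Hmox1 was at 64.4 ± 6.28, 78.0 ± 28.9, 84.0 ± 15.02 and 138 ± 73.1 CPM. Ptgs2, a prostaglandin enzyme gene often read as a ferroptosis marker, was at 54.7 ± 12.7, 95.4 ± 31.5, 76.5 ± 35.9 and 124 ± 73.8 CPM. Both were highest in HI1, at 222 and 208 CPM.

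Lists of ferroptosis genes were not called in any comparison. For the 35 drivers, preset camera gave adjusted p = 0.212 to 0.983, and the lowest adjusted p = 0.566 with an estimated correlation. The drivers' median log2 change was -0.04 in HC against MC while their mean was 0.14 and the test pointed up. In the altitude average the median was -0.04, the mean 0.03 and the test pointed down. For the 30 suppressors, preset camera gave adjusted p = 0.0625 to 0.681, and the lowest adjusted p = 0.47 with an estimated correlation. In MI against MC the suppressors' median was -0.05, their mean 0.03 and the test pointed down. Iron-handling genes were called at a single comparison, the altitude average, with a median of 0.07 (preset camera adjusted p = 0.0296). Their adjusted p = 0.482 with an estimated correlation. Of 25 members, 4 passed when adjusted over the list alone and 0 over all genes: Tfrc (log2 0.77), the metal transporter gene Slc39a14 (0.34) and the metal reductase gene Steap1 (0.54) higher, and Slc40a1 (-0.76) lower.

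In mice given vehicle, simulated altitude was accompanied by shifts of whole groups of genes. Genes of red blood cells, fat cells, neutrophils, inflammation and cell division stood higher in HC tumours than in MC tumours. Genes of mast cells, dendritic cells and antigen presentation on MHC class II stood lower. These calls are from preset camera, and 0 lists were called with an estimated correlation. The higher groups were not higher in every mouse: HC1 scored -0.66 for neutrophils and -0.63 for inflammation, below MC2 (-0.24 and -0.28). No single gene passed the threshold in edgeR, although 1829 of 15269 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.156. DESeq2 called 314 genes and limma-voom 0, as did limma on FPKM. A block for the replicate number gave 13 genes, 10 higher and 3 lower; the labels name no pairing, but same-number libraries of HC and MC deviated together (correlations of 0.278, 0.153 and 0.209). The groups did not overlap for 21.7% of genes, against 10% by chance. The 5 genes with the smallest p, none of which passed (adjusted p = 0.156 for each), were the alpha-globin gene Hba-a1 (log2 2.00, SE 0.27), the beta-globin gene Hbb-bs (1.78, SE 0.29), Vash1, which encodes an inhibitor of vessel growth (-0.60), Gpr183, a receptor gene that guides lymphocytes (-1.13), and the small GTPase gene Rhou (-0.64).

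The 7 erythroid genes, those of hemoglobin, heme synthesis and the red-cell membrane, had a median log2 change of 1.87 in HC against MC (preset camera adjusted p = 3.5e-15). Their adjusted p = 0.11 with an estimated correlation. Of the 7, 5 passed when adjusted over the list alone and 0 over all genes, led by Hba-a1, Hbb-bs, Hba-a2 (2.09) and the heme-synthesis gene Alas2 (2.13). All 14 immediate-early genes, which answer growth and stress signals within minutes, were higher (median 0.26, preset camera adjusted p = 6.4e-06). Their adjusted p = 0.165 with an estimated correlation. The transcription factor gene Egr1 (0.94), the mRNA-decay gene Zfp36 (0.46) and Fosb (0.88) passed when adjusted over the list alone, and 0 of the list over all genes. All 7 mast-cell genes were lower (median -1.38, preset camera adjusted p = 6.5e-09, and adjusted p = 0.208 with an estimated correlation), 6 of them when adjusted over the list alone and 0 over all genes. All 32 proliferation genes were higher by a median of 0.29 (preset camera adjusted p = 3.9e-11, and adjusted p = 0.731 with an estimated correlation). None of those passed when adjusted over the list alone or over all genes, the mitotic kinase gene Cdk1 (0.33) and the nucleotide-supply gene Rrm2 (0.47) among them. The low score of MC3 (-0.46) weighs in this, and HC3 (-0.10) scored below MC1 (-0.02) and MC2 (0.00).

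Inflammatory genes had a median of 0.51 (preset camera adjusted p = 1.5e-06, and adjusted p = 0.731 with an estimated correlation) and neutrophil genes a median of 1.15 (preset camera adjusted p = 4.9e-07, and adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 5 inflammatory and 4 neutrophil genes passed, and 0 of either over all genes. MHC class II genes had a median of -0.33 (preset camera adjusted p = 0.000109, and adjusted p = 0.731 with an estimated correlation), with 0 of 10 higher. Adipocyte genes had the widest shift, a median of 2.78, with leptin (Lep) at 4.16 and the lipid carrier gene Fabp4 at 2.53 (preset camera adjusted p = 6.9e-11, and adjusted p = 0.564 with an estimated correlation). All 11 of those passed when adjusted over the list alone and 0 over all genes, and the adipocyte score was 2.22 in HC1 and 1.57 in HC2 but -0.74 in HC3. In all, preset camera called 12 of 46 lists, 9 higher and 3 lower, and none was called with an estimated correlation or by fry. Leaving out HI1, whose spread enters the fit, gave 40 called genes, and leaving out HC1 gave 21 called lists.

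In mice given IOX2, altitude was accompanied by lower levels of vessel genes and higher levels of glycolysis genes. Markers of endothelial cells and of the pericytes and muscle cells that wrap vessels stood lower in HI tumours than in MI tumours. Glycolysis enzymes, HIF target genes, antioxidant genes and core clock genes stood higher, though not in every mouse: HI3 scored below an MI library in each of these lists. Genes of ribosomes and epithelial tumour cells stood higher too, and those of collagen matrix, B cells and the mitochondrial genome lower. These calls are from preset camera, and 0 lists were called with an estimated correlation. Library MI1 had the highest endothelial and mural scores, 0.38 and 0.63, against -0.02 and -0.01 in MI2. No gene passed the threshold in edgeR (smallest adjusted p = 0.0589, with 2321 genes at an unadjusted p under 0.05). DESeq2 called 381 genes, limma-voom 0 and limma on FPKM 0. The groups did not overlap for 14.6% of genes, against 10% by chance. The 5 genes with the smallest p, which did not pass, included 4 genes of vessels: Vash1 (log2 -0.75, adjusted p = 0.0589), the endothelial receptor gene Cd93 (-0.75, adjusted p = 0.0589), the adhesion molecule gene Mcam (-0.69, adjusted p = 0.0755) and the endothelial repressor gene Bcl6b (-1.02, adjusted p = 0.0755). The other was Zfp36l2, which encodes an mRNA-decay factor (0.53, adjusted p = 0.0755).

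Endothelial markers had a median log2 change of -0.58 in HI against MI, with 17 of 18 lower (preset camera adjusted p = 8.2e-12). Their adjusted p = 0.405 with an estimated correlation. When adjusted over the list alone, 11 were lower and 1 higher, against 0 over all genes, with the junction genes Cdh5 (-0.69) and Pecam1 (-0.52), the receptor gene Tie1 (-0.60) and the transcription factor gene Sox18 (-0.71) in front. Mural-cell genes had a median of -0.57 (preset camera adjusted p = 0.000122, and adjusted p = 0.405 with an estimated correlation), led by the pericyte genes Rgs5 (-1.14) and Pdgfrb (-0.45). Of the mural genes, 3 passed when adjusted over the list alone and 0 over all genes. In HC against MC the endothelial list had not been called, and there the stored clotting factor gene Vwf had a log2 change of 0.91. Glycolysis genes had a median of 0.40 with 17 of 19 higher (preset camera adjusted p = 1.2e-06, and adjusted p = 0.622 with an estimated correlation). HIF targets had a median of 0.23 (preset camera adjusted p = 0.00172, and adjusted p = 0.67 with an estimated correlation). The scores of both lists were highest in HI1, at 0.44 and 0.49. The HIF target scores of HI2 (0.06) and HI3 (-0.06) were below that of MI2 (0.07). The glycolysis score of HI3 (0.05) was below that of MI2 (0.09).

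Antioxidant and glutathione genes had a median of 0.13 (preset camera adjusted p = 0.000154, and adjusted p = 0.581 with an estimated correlation), though HI3 (-0.09) scored below MI1 (-0.04). Clock genes had a median of 0.46 (preset camera adjusted p = 0.000527, and adjusted p = 0.464 with an estimated correlation), with 7 passing when adjusted over the list alone and 0 over all genes. The repressor genes Ciart (1.42), Bhlhe41 (0.57) and Cry2 (0.53) were among them. Type I interferon genes were lower in 22 of 23 cases (median -0.27, preset camera adjusted p = 7.5e-07, and adjusted p = 0.516 with an estimated correlation). Chaperones of the unfolded protein response were lower in 17 of 18 (median -0.21, preset camera adjusted p = 1.5e-05, and adjusted p = 0.427 with an estimated correlation), led by Dnajb9 (-0.99) and Dnajc3 (-0.54). Erythroid genes were higher in 7 of 7 (median 1.03, preset camera adjusted p = 5.1e-08, and adjusted p = 0.405 with an estimated correlation), 6 of them when adjusted over the list alone and 0 over all genes. Ribosomal protein genes were higher in 24 of 24 (median 0.20, preset camera adjusted p = 7.5e-07, and adjusted p = 0.622 with an estimated correlation) and epithelial tumour genes in 14 of 16 (median 0.16, preset camera adjusted p = 0.000874, and adjusted p = 0.556 with an estimated correlation). Low ribosomal scores in MI1 (-0.31) and MI3 (-0.21) weigh in this, and HI3 (-0.08) scored below MI2 (-0.01). Collagen-matrix genes were lower in 21 of 22 (median -0.21, preset camera adjusted p = 0.00133, and adjusted p = 0.622 with an estimated correlation). Mitochondrial genes of the respiratory chain had a median of -0.39 (preset camera adjusted p = 0.0108, and adjusted p = 0.67 with an estimated correlation). MI3 scored 0.91 in this list, while MI2 (-0.37) scored below every HI library. The B-cell and plasma-cell list had a median of -5.22 (preset camera adjusted p = 0.00287, and adjusted p = 0.622 with an estimated correlation), with a score of 5.54 in MI1. Preset camera called 21 lists, 10 higher and 11 lower, and none was called with an estimated correlation or by fry. Leaving out MI2 gave 520 called genes, and leaving out HC3 or HI3 gave 1 each.

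Averaged over treatment, Vash1, Cd93 and Mcam, which are expressed in the endothelium that lines blood vessels, were lower at simulated altitude. Higher there were globin genes and Cxcl1, which encodes a chemokine that attracts neutrophils. In edgeR 76 genes were called, 36 higher and 40 lower (2641 at an unadjusted p under 0.05). Of the 76, 14 had an unadjusted interaction p under 0.05, and 0 passed when the interaction was adjusted over the 76.

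By the naming rule, the 5 genes with the smallest adjusted p all fell at altitude. Vash1, which encodes vasohibin, a brake on vessel growth made by endothelium, fell by 0.68 on the log2 scale (SE 0.07, adjusted p = 0.00531). Its levels were 34.2 ± 2.72 CPM in MC, 33.5 ± 3.10 in MI, 22.6 ± 0.883 in HC and 19.9 ± 0.862 in HI. Cd93, a receptor gene of endothelium and myeloid cells, fell by 0.64 (adjusted p = 0.00858), from 100.4 ± 1.91 CPM in MC and 99.2 ± 13.0 in MI to 69.3 ± 5.12 in HC and 58.9 ± 2.87 in HI. Mcam, which encodes a vascular adhesion molecule, fell by 0.55 (adjusted p = 0.0224), from 118 ± 2.74 and 125 ± 13.0 CPM to 88.7 ± 7.92 and 76.9 ± 7.03. The cell-cycle gene Ccnd2 fell by 0.61 and the small GTPase gene Rhou fell by 0.56 (adjusted p = 0.0224 each). Leaving out MC2 or MC3 ended the calls of Mcam, Ccnd2 and Rhou, leaving out HC1 or HC3 those of Ccnd2 and Rhou, and leaving out MI3 or HI2 that of Rhou (adjusted p from 0.0502 to 0.0838), while Vash1 and Cd93 were called without any 1 library. Over all alternatives the adjusted p of the 5 genes ran from 9.4e-18 with DESeq2 to 0.15 without both MI1 and MI3.

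Other called genes were chosen after their values were seen, and no test was made of whether the calls gather in any function beyond the lists. Lower at altitude were the Notch ligand gene Dll4 (log2 -0.45) and the Notch target gene Hey1 (-1.30), the endothelial genes Bcl6b (-0.66), Pcdh12 (-0.73) and Scarf1 (-0.58), the basement-membrane gene Nid2 (-0.66), the growth-factor binder gene Igfbp3 (-1.03), the Wnt-pathway transcription factor gene Lef1 (-1.95), the alarmin gene Il33 (-1.18) and the receptor gene Kit (-0.61). Higher were the neutrophil attractant gene Cxcl1 (1.68), the matrix protease gene Mmp3 (0.95), the AP-1 gene Fosl1 (1.06), the hormone-like gene Pthlh (1.03), the polyamine enzyme gene Odc1 (0.42), the glucocorticoid-activating enzyme gene Hsd11b1 (1.38) and the pentraxin gene Nptx1 (1.23). Cxcl1 stood at 8.86 ± 0.263 CPM in MC and 12.2 ± 1.31 in MI against 29.5 ± 13.1 in HC and 37.2 ± 17.2 in HI. Dll4 stood at 23.4 ± 0.0985 and 22.7 ± 0.811 CPM against 17.1 ± 1.36 and 16.7 ± 1.81. Hba-a1, Hba-a2, Hbb-bs and Alas2 were called as well (log2 1.51, 1.43, 1.43 and 1.70).

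**Figure D1:**
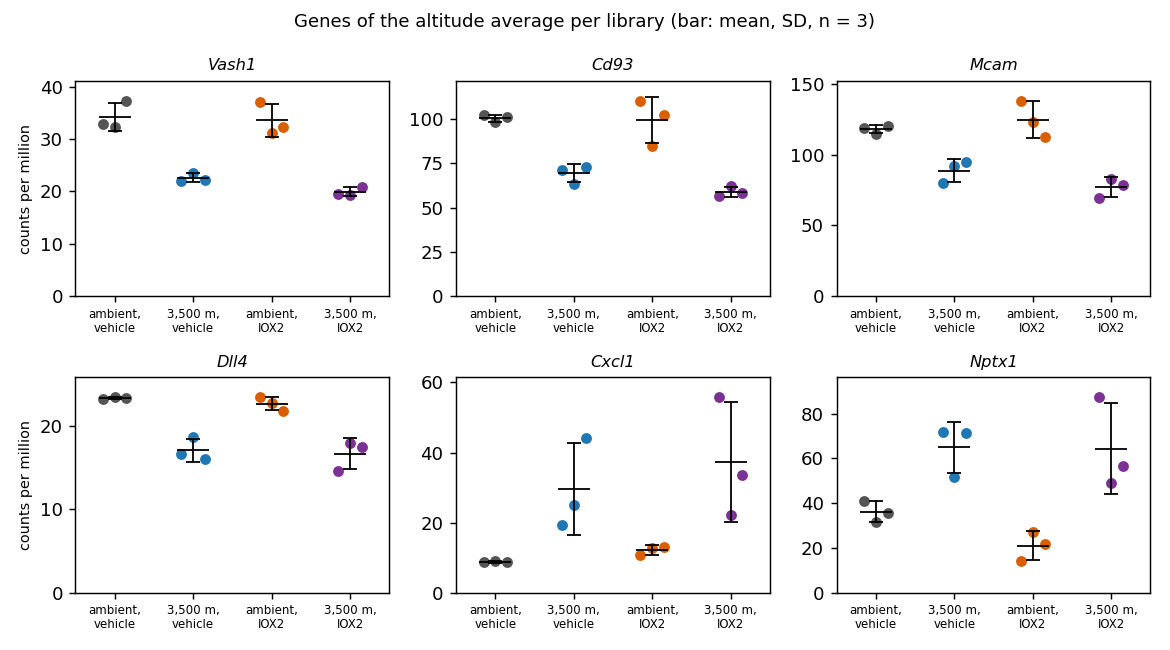
CPM (linear axis from 0) of 6 genes called in the altitude average, for MC, HC, MI and HI from left to right; points are the 3 mice of a group and bars are the mean and SD. Vash1, Cd93, Mcam and Dll4 are lower in both altitude groups than in both ambient groups, with every HC and HI mouse below every MC and MI mouse, while Cxcl1 and Nptx1 are higher.

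Among lists, endothelial markers had a median of -0.29 in the altitude average (preset camera adjusted p = 0.000121, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone 11 of the 18 were lower, led by Sox18 (-0.43), Cdh5 (-0.37) and the VEGF receptor gene Kdr (-0.44), and 1 higher, Vwf (0.78), against 0 over all genes. Inflammatory genes had a median of 0.45 (preset camera adjusted p = 2.2e-08, and adjusted p = 0.478 with an estimated correlation), with 10 passing when adjusted over the list alone and 1 over all genes. Neutrophil genes were higher in 16 of 16 (median 0.71, preset camera adjusted p = 4.8e-07, and adjusted p = 0.482 with an estimated correlation). Mast-cell genes were lower in 7 of 7 (median -0.85, preset camera adjusted p = 4.8e-07, and adjusted p = 0.478 with an estimated correlation), 6 when adjusted over the list alone and 1 over all genes. Targets of the stress factor ATF4 had a median of 0.25 (preset camera adjusted p = 0.000849, and adjusted p = 0.501 with an estimated correlation), with the serine-pathway genes Shmt2 (0.30) and Phgdh (0.28) higher when adjusted over the list alone and 0 of the list over all genes. Fatty-acid oxidation genes had a median of 0.07 (preset camera adjusted p = 0.00976, and adjusted p = 0.65 with an estimated correlation), with the mitochondrial enzyme genes Acaa2 (0.41) and Cpt1a (0.72) passing when adjusted over the list alone and 0 over all genes. Erythroid genes were higher in 7 of 7 (median 1.43, preset camera adjusted p = 7.9e-18, and adjusted p = 0.0686 with an estimated correlation). Adipocyte genes were higher in 11 of 11 (median 1.70, preset camera adjusted p = 1.7e-07, and adjusted p = 0.482 with an estimated correlation), 11 of them when adjusted over the list alone and 0 over all genes, though the score was -0.74 in HC3 and -1.46 in HI3. The B-cell and plasma-cell list had a median of -2.06 (preset camera adjusted p = 0.00994, and adjusted p = 0.666 with an estimated correlation). MI1 weighs in this, with a score of 5.54 against -0.16 in MI2 and -0.25 in MI3. HC2 (0.14) and HI1 (-0.02) scored above MI2. Ribosomal protein genes were higher in 23 of 24 (median 0.07, preset camera adjusted p = 0.0124, and adjusted p = 0.905 with an estimated correlation). Of 46 lists, preset camera called 14 higher and 7 lower, and 0 were called with an estimated correlation, while fry called 1, the erythroid list. The count of 76 genes became 17 without MC1, 2 without MC2, 2 without MC3, 10 without MI1, 203 without MI2, 7 without MI3, 9 without HC1, 7 without HC3, 17 without HI1, 8 without HI2 and 339 without HI3. DESeq2 called 866 genes, limma-voom 20, and limma on FPKM 52 or 55.

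At ambient altitude IOX2 raised the genes of red-cell hemoglobin and no others that passed. The alpha-globin and beta-globin genes encode the chains of the oxygen carrier of red cells. Genes of T cells, natural killer cells and immune checkpoints stood higher as groups, and genes of ribosomes, of the nuclear-encoded respiratory chain and of epithelial tumour cells stood lower. Of these groups only the red-cell genes were called with an estimated correlation. In edgeR 4 genes rose and 0 fell (1434 at an unadjusted p under 0.05, with DESeq2 calling 20, limma-voom 0 and limma on FPKM 4). The groups did not overlap for 11.1% of genes, against 10% by chance. Hba-a1 rose by 2.51 on the log2 scale (SE 0.27, adjusted p = 0.0195). This was 5.70-fold, with 3.90 to 8.34 spanning 2 SE either side, from 5.08 ± 0.105 CPM in MC to 29.0 ± 4.89 in MI (SD, n = 3). Hbb-bs rose by 2.29 (SE 0.30, adjusted p = 0.0271), from 11.2 ± 0.219 to 54.6 ± 7.97 CPM. Hba-a2 rose by 2.89 (SE 0.36, adjusted p = 0.0271), from 1.09 ± 0.452 to 8.11 ± 1.31 CPM, and Hbb-bt by 2.46 (SE 0.32, adjusted p = 0.0271), from 1.84 ± 0.411 to 10.1 ± 2.39 CPM. Each of the 4 was higher in 3 of 3 MI mice than in every MC mouse. The copies within each pair are nearly identical in sequence, so the split of reads between them is uncertain. Hba-a1 was not called without MC1, MC2, MC3, MI1 or HI2 (adjusted p from 0.0510 to 0.253), Hba-a2 also not without HC3 (0.0517 to 0.269), and Hbb-bs and Hbb-bt also not without HC3 or MI2 (0.0516 to 0.320). Over all alternatives the adjusted p of the 4 ran from 2.4e-16 with DESeq2 to 0.344 with limma-voom. The count was 0 without MC1, MC2, MC3, MI1 or HI2 and 1 without HC3.

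The erythroid list had a median log2 change of 2.46 in MI against MC (preset camera adjusted p = 2.8e-27). It was the 1 list that also passed with an estimated correlation (adjusted p = 0.0191 with an estimated correlation) and by fry. Of its members, 5 passed when adjusted over the list alone and 4 over all genes. T-cell genes had a median of 0.88 with 14 of 14 higher (preset camera adjusted p = 1.3e-07, and adjusted p = 0.49 with an estimated correlation). Cytotoxic genes of natural killer cells had a median of 0.76 with 13 of 13 higher (preset camera adjusted p = 2.2e-05, and adjusted p = 0.49 with an estimated correlation). Checkpoint and regulatory T-cell genes had a median of 0.57 with 14 of 14 higher (preset camera adjusted p = 2.8e-05, and adjusted p = 0.49 with an estimated correlation), led by the checkpoint receptor gene Ctla4 (1.46), the 1 member passing when adjusted over the list alone. The B-cell and plasma-cell list had a median of 5.33 (preset camera adjusted p = 0.00098, and adjusted p = 0.604 with an estimated correlation). Its score was 5.54 in MI1 against -0.16 in MI2 and -0.25 in MI3. The T-cell score was 1.35 in MI1, 0.17 in MI2 and -0.16 in MI3, the last below MC3 (-0.15). Natural killer scores were 0.73, 0.35 and -0.06 in MI1 to MI3, and checkpoint scores 0.70, 0.18 and 0.06. Nuclear genes of the respiratory chain were lower in 38 of 40 (median -0.18, preset camera adjusted p = 1.1e-12, and adjusted p = 0.49 with an estimated correlation), with Ndufb8 (-0.27) and Cox5b (-0.29) in front. Mitochondrial genes of the same chain had a median of 0.25 (preset camera adjusted p = 0.00712, and adjusted p = 0.656 with an estimated correlation) and a score of 0.91 in MI3. Ribosomal protein genes were lower in 24 of 24 (median -0.28, preset camera adjusted p = 1.8e-14, and adjusted p = 0.49 with an estimated correlation). Single libraries weigh in both the nuclear and the ribosomal shift. MC3 scored 0.22 and 0.34 in these lists, against at most 0.04 and 0.02 in MC1 and MC2, while MI2 scored -0.02 and -0.01, MI3 -0.15 and -0.21 and MI1 -0.08 and -0.31. The log2 deviations of MC3 and MI3 also followed GC content in opposite directions, with rank correlations of 0.28 and -0.51, though MI2 had 0.27. Epithelial tumour genes were lower in 15 of 16 (median -0.19, preset camera adjusted p = 0.000196, and adjusted p = 0.49 with an estimated correlation), with the lowest score in MI1 (-0.34). Glycolysis genes had a median of -0.11 (preset camera adjusted p = 0.0402, and adjusted p = 0.656 with an estimated correlation). HIF targets were not called: their median was -0.07, their mean 0.04 and the test pointed down (preset camera adjusted p = 0.635, and adjusted p = 0.899 with an estimated correlation). Preset camera called 22 lists, 18 higher and 4 lower, and 13 without MI1.

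At simulated altitude IOX2 was again accompanied by higher globin genes, though none passed over all genes. Endothelial, interferon, fat-cell and stromal genes stood lower in HI tumours than in HC tumours, and glycolysis genes, HIF targets and T-cell genes stood higher. With an estimated correlation only the erythroid list was called. In edgeR 0 genes were called (740 at an unadjusted p under 0.05, smallest adjusted p = 0.577), while DESeq2 called 22, limma-voom 0 and limma on FPKM 0. The groups did not overlap for 11.4% of genes, against 10% by chance. The 5 genes with the smallest p, none passing, were Hbb-bt (log2 1.83, adjusted p = 0.577), Hba-a1 (1.55, adjusted p = 0.577), Hbb-bs (1.58, adjusted p = 0.766), the lymphocyte-guiding gene Gpr183 (0.92, adjusted p = 0.964) and the adaptor gene Hsh2d (-0.72, adjusted p = 0.964). Hba-a1 stood at 20.3 ± 7.18 CPM in HC and 59.3 ± 19.7 in HI, and Hbb-bs at 38.6 ± 15.3 and 115 ± 45.7.

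The erythroid list was called in HI against HC with a median of 1.58 (preset camera adjusted p = 1.1e-29, and adjusted p = 0.0123 with an estimated correlation) and by fry. All 7 members passed when adjusted over the list alone and 0 over all genes. Endothelial markers were lower in 18 of 18 (median -0.38, preset camera adjusted p = 6.9e-16, and adjusted p = 0.285 with an estimated correlation). When adjusted over the list alone 7 of them passed and 0 over all genes, with Tie1 (-0.54), Cdh5 (-0.50), Esam (-0.49) and Pecam1 (-0.36) in front. Interferon genes were lower in 21 of 23 (median -0.27, preset camera adjusted p = 7.6e-12, and adjusted p = 0.333 with an estimated correlation), 5 of them when adjusted over the list alone and 0 over all genes, with the sensor gene Rigi (-0.35), Isg15 (-0.48) and the factor gene Irf7 (-0.45) in front. HIF targets had a median of 0.23 (preset camera adjusted p = 0.000236, and adjusted p = 0.521 with an estimated correlation). Glycolysis genes had a median of 0.23 with 18 of 19 higher (preset camera adjusted p = 1.6e-06, and adjusted p = 0.47 with an estimated correlation). The HIF target and glycolysis scores rest on HC1 (-0.45 and -0.44) and HI1 (0.49 and 0.44). Among the other libraries the glycolysis scores overlapped, at 0.18 and 0.08 in HC2 and HC3 against 0.13 and 0.05 in HI2 and HI3. T-cell genes had a median of 0.42 with 14 of 14 higher (preset camera adjusted p = 0.000457, and adjusted p = 0.521 with an estimated correlation), though HI1 scored -0.29. Adipocyte genes were lower in 11 of 11 (median -0.82, preset camera adjusted p = 0.000802, and adjusted p = 0.521 with an estimated correlation). Collagen-matrix genes were lower in 18 of 22 (median -0.15, preset camera adjusted p = 0.000144, and adjusted p = 0.47 with an estimated correlation). Fibroblast genes were lower in 12 of 14 (median -0.26, preset camera adjusted p = 0.0239, and adjusted p = 0.607 with an estimated correlation) and mural-cell genes in 9 of 11 (median -0.24, preset camera adjusted p = 0.0383, and adjusted p = 0.47 with an estimated correlation). Preset camera called 23 lists, 10 higher and 13 lower.

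Averaged over altitude, IOX2 raised the 4 globin genes and Alas2, which starts heme synthesis in red-cell precursors. In edgeR 6 genes were called higher and 0 lower (782 at an unadjusted p under 0.05, with DESeq2 calling 11, limma-voom 4 and limma on FPKM 5). Hbb-bt and Hba-a2 met every condition of the naming rule; Hba-a1, Hbb-bs and Alas2, also among the 5 smallest p, passed the threshold with overlapping groups (MI against HC). The log2 changes were 2.03 for Hba-a1 (SE 0.19, adjusted p = 0.00357), 1.93 for Hbb-bs (SE 0.21, adjusted p = 0.00495), 2.14 for Hbb-bt (SE 0.22, adjusted p = 0.00481) and 2.23 for Hba-a2 (SE 0.25, adjusted p = 0.00563). Alas2 stood at 0.977 ± 0.312 CPM in MC, 5.91 ± 2.30 in MI, 4.30 ± 1.38 in HC and 14.3 ± 6.40 in HI. The globin calls held without any 1 library. The call of Alas2 ended without MC1, MC2, MC3, MI1, MI2, HC2 or HC3 (adjusted p from 0.0506 to 0.161). Over all alternatives the adjusted p of Alas2 ran from 3.1e-11 to 0.21.

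As a list, erythroid genes had a median of 2.03 in the IOX2 average (preset camera adjusted p = 1.6e-62, and adjusted p = 0.00104 with an estimated correlation), with 6 passing when adjusted over the list alone and 5 over all genes. T-cell genes had a median of 0.64 with 14 of 14 higher (preset camera adjusted p = 7.1e-12, and adjusted p = 0.477 with an estimated correlation), 5 of them when adjusted over the list alone and 0 over all genes. Natural killer genes had a median of 0.52 with 13 of 13 higher (preset camera adjusted p = 3.8e-09, and adjusted p = 0.195 with an estimated correlation), 3 of them when adjusted over the list alone and 0 over all genes. MI1 stands apart in both lists (1.35 and 0.73), and T-cell scores were 0.17 in MI2, -0.16 in MI3 and -0.29 in HI1. Inflammatory genes had a median of 0.44 (preset camera adjusted p = 2.2e-08, and adjusted p = 0.477 with an estimated correlation). Every MI library scored above every MC library in this list. At simulated altitude HC1 (-0.63) and HI1 (1.00) stand apart, and HC2 (0.59) scored above HI2 (0.24) and HI3 (0.36). Nuclear respiratory-chain genes were lower in 40 of 40 by a median of -0.12 (preset camera adjusted p = 2.7e-17, and adjusted p = 0.477 with an estimated correlation). Preset camera called 15 lists, 8 higher and 7 lower.

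**Figure D2:**
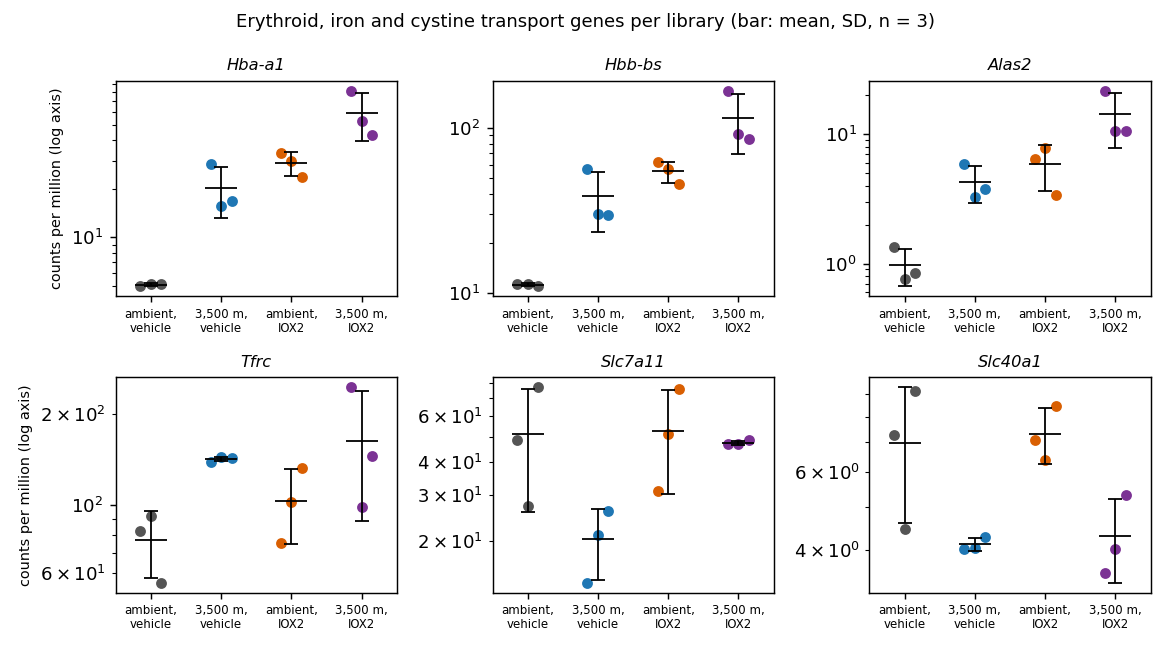
CPM (log axis) of 3 red-cell genes (Hba-a1, Hbb-bs, Alas2) and of Tfrc, Slc7a11 and Slc40a1 in MC, HC, MI and HI from left to right; points are the 3 mice of a group and bars are the mean and SD. Hba-a1 means run from 5.08 in MC through 20.3 in HC and 29.0 in MI to 59.3 in HI, and Slc7a11 is lowest in HC at 20.4.

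Whether IOX2 acted differently at altitude was tested as the interaction. No gene passed in edgeR (1254 at an unadjusted p under 0.05, smallest adjusted p = 0.596), DESeq2 called 32, limma-voom 0 and limma on FPKM 0. The 5 genes with the smallest p, none passing (adjusted p = 0.596 each), were the hypoxia-responsive mTOR inhibitor gene Ddit4 (log2 0.89), the ubiquitin ligase gene Rnf125 (-1.09), Hsh2d (-1.05), Phf11d (-0.73) and Mertk, a receptor gene for clearing dead cells (-1.63). Erythroid genes had a median interaction of -0.71 and were not called (preset camera adjusted p = 0.109, and adjusted p = 0.622 with an estimated correlation). Preset camera called 21 lists, 7 higher and 14 lower, and none with an estimated correlation or by fry. Endothelial markers had a median interaction of -0.58 (preset camera adjusted p = 1e-10, and adjusted p = 0.554 with an estimated correlation). Glycolysis genes had a median interaction of 0.37 (preset camera adjusted p = 7e-06, and adjusted p = 0.566 with an estimated correlation). Leaving out MI2 gave 2 called genes.

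**Figure D3:**
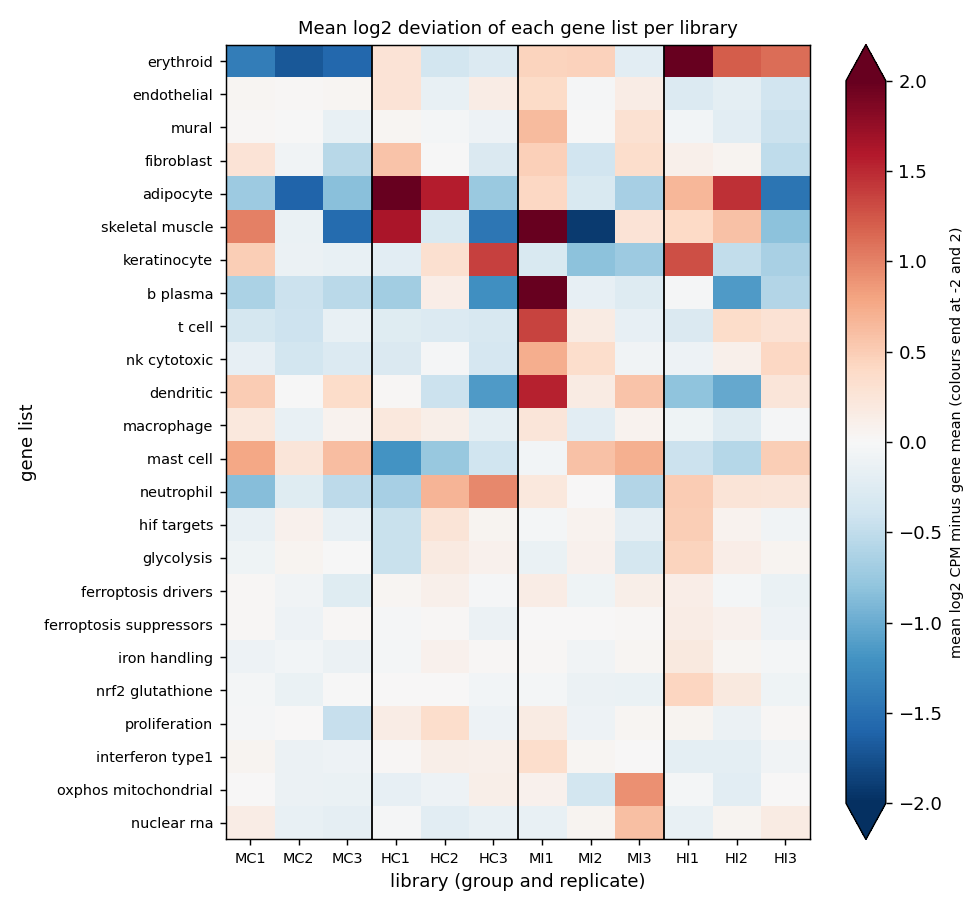
Scores of 24 gene lists (vertical) in each of the 12 libraries (horizontal), as the mean log2 difference of the members from their mean over libraries; colours end at -2 and 2. Erythroid scores run from -1.70 in MC2 to 2.00 in HI1, while the B-cell and plasma-cell score is 5.54 in MI1 and the adipocyte score is 2.22 in HC1.

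The altitude and IOX2 effects, each measured against the MC tumours, were compared across genes. Red-cell genes had higher means in HC and in MI than in MC. Across 15269 genes the covariance of the log2 changes was 0.0759 and their correlation 0.457. Libraries simulated without effects gave a covariance of 0.0542 on average (0.0499 to 0.0594 over 100 simulations), which comes from the shared MC libraries, so the observed covariance was 0.0217 above it. The covariance was 0.0523 without MI1, 0.0502 without both MI1 and MI3, 0.122 without MC1 and 0.1099 without MC2. The simulations were made for all libraries only, so the excess in these settings is not known. These values spread more widely than the 100 simulations, so the size of the excess with all libraries is uncertain too. The simulated correlation averaged 0.497 and reached 0.535, above the observed one. The covariance, the measure set beforehand, was above all 100 simulations, whereas the correlation was below their average. With these measures pointing different ways, similarity beyond the shared libraries was not shown. No gene was called in both comparisons in edgeR, since altitude with vehicle had 0 calls (1829 genes at an unadjusted p under 0.05, 314 calls by DESeq2). Between effects that share no library, altitude with vehicle and altitude with IOX2 correlated at 0.292 across genes, and IOX2 at ambient and at simulated altitude at -0.161. Genes are not independent replicates, so these correlations carry no p.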

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

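In the weighing of library MI3, the tests of GC content, of gene length and of adjacent tissue were chosen only after that library was seen to stand apart, the test of GC content before its own value was seen.

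Between the altitudes, the effect of IOX2 differed for 21 gene lists in a test of the interaction with preset camera, 7 higher and 14 lower at simulated altitude. None of the 21 was called with an estimated correlation (adjusted p = 0.554 to 0.716) or by fry. Metabolic and tumour-cell lists had higher medians: HIF targets 0.23, glycolysis 0.37, antioxidant and glutathione genes 0.18, nuclear respiratory-chain genes 0.12, ribosomal proteins 0.26 and epithelial tumour genes 0.19. Mast-cell genes were higher as well, at 0.93. Stress and growth lists had lower medians: unfolded protein response -0.24, heat shock -0.23, proliferation -0.35, immediate-early genes -0.21 and mitochondrial respiratory-chain genes -0.41. Vessel and stroma lists were lower: endothelial markers -0.58, mural cells -0.56, fibroblasts -0.48 and collagen matrix -0.39. Immune and tissue lists were lower too: type I interferon genes -0.43, checkpoint and regulatory T-cell genes -0.23, neutrophil precursors -3.07, B and plasma cells -5.96 and adipocytes -1.98. MI1 stood apart in the widest of these. Its B and plasma score was 5.54 against -0.16 in MI2 and -0.25 in MI3. The neutrophil precursor score was 1.95 in MI1 against 0.36 in MI2 and -0.39 in MI3. Mean B and plasma scores were -0.54 in MC, -0.60 in HC and -0.58 in HI, far closer to MI2 and MI3 than to MI1. The size of the B and plasma interaction thus comes mainly from MI1. How much of the neutrophil precursor interaction rests on MI1 was not tested. Leaving out MI1 alone, preset camera called 18 lists. Without both MI1 and MI3, an alternative chosen after seeing the data, 13 lists were called. No gene passed the interaction in edgeR. All 100 of 100 drawn splits of the libraries, the real one included, gave at least as many genes (real 0, highest other 0); any split reaches a count of 0, so the splits decide nothing here.

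Library MI3 stood apart within its group on the measures given here and enters those interactions. Not every measure set it apart: the lowest correlation of log2 CPM within the group was between MI1 and MI2, at 0.970. Its mitochondrial share was 2.96% of counts against a median of 1.89%, its score for nuclear-retained RNAs was 0.59, and its Acsl4 and Hif1a levels, 1033 and 721 CPM, were the highest of all libraries. A GC content bias of that library may account for part of its difference: across genes, its log2 deviations followed GC content with a Spearman correlation of -0.51, the strongest of the 12 libraries. Gene length bias stays open, since the correlation with length, 0.27, was the strongest of the 12 but under the 0.3 set for the test. Adjacent tissue in the tumour piece stays open as well, since 3 of 5 lists (skeletal muscle, adipocytes, keratinocytes, nerve, B cells) scored above the median of the other 11 libraries in MI3 and none was highest there. No biological explanation was tested for this library, which shares its group with 2 others.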

How the results depend on the processing

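The GC and length correction, the fit without MI1 and MI3 and the legacy FALSE version of the edgeR fit were chosen after seeing the data, and where a count moved the cause was not tested unless named. For the called genes named by rule and the erythroid median, the only list median weighed singly, 417 values under alternatives kept their direction and side of the threshold, 78 kept the direction but missed the threshold and 0 reversed. Other lists entered only the counts of calls. Of the counts and the covariance under alternatives, 283 stayed within their limits and 70 moved. DESeq2 called more genes in every comparison: 314 and 381 for altitude with vehicle and with IOX2, 20 and 22 for IOX2 at ambient and simulated altitude, 32 for the interaction, and 866 and 11 for the altitude and IOX2 averages. Without a filter, altitude gave 2 genes with vehicle, 16 with IOX2 and 166 averaged. Altitude with IOX2 gave 1 gene with DESeq2 size factors and 2 with at least 1 CPM in 3 libraries. The 6 libraries compared, fitted alone, gave 63 for altitude with vehicle and 2 for IOX2 at ambient altitude. With limma-voom IOX2 at ambient altitude gave 0 genes and the altitude average 20. Removing the GC and length trend gave 4 genes for altitude with IOX2 and 159 for the altitude average, which included 72 of the 76. Without MI1 and MI3, IOX2 at ambient altitude gave 0 genes, the altitude average 3, the interaction 13 lists and the IOX2 average 23 lists, with fewer samples. With legacy FALSE, altitude with vehicle gave 2 genes. A replicate block gave 13 genes for altitude with vehicle, 3 for IOX2 at simulated altitude and 155 for the altitude average. Same-number libraries correlated above 0.1 in 11 of 18 pairs (lowest -0.192), and 6 of 12 libraries correlated best with their own number. The median correlation was 0.142 for same-number pairs and -0.0543 for other pairs, so a factor shared by replicate number cannot be excluded. The labels name no pairing and some same-number pairs were negative, so the main fit has no block. In HC against MC alone all 3 pairs exceeded 0.1 (0.278, 0.153 and 0.209), seen after the block's calls were known, and lists called there were 13 with the block. Lists called fell from 12, 21, 22, 23, 21, 21 and 15 (the comparisons in the order above) to 0, 0, 1, 1, 0, 0 and 1 with an estimated correlation, and to 0, 0, 1, 1, 0, 1 and 1 by fry, since genes of a list move together. The covariance of the altitude and IOX2 effects, 0.0759, was 0.0243 on FPKM plus 1, 0.0415 on FPKM plus 0.1 and 0.0502 without MI1 and MI3.

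Leaving out each library in turn, counts ran from 0 (11 libraries) to 40 for altitude with vehicle, 0 to 520 for altitude with IOX2, 0 to 6 for IOX2 at ambient altitude, 0 to 2 for the interaction and 2 to 339 for the altitude average. Lists ran from 12 to 21 for altitude with vehicle and from 13 to 22 for IOX2 at ambient altitude, and the covariance from 0.0523 to 0.122. IOX2 at simulated altitude gave 0 without any 1 library in edgeR (740 genes at an unadjusted p under 0.05 with all libraries, 22 calls by DESeq2), and the IOX2 average 4 to 6. Depth did not differ much between libraries, the lowest being HC1 at 31661685 counts, and genes under about 0.0948 CPM there were not detectable.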

Other observations

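The tests of whole blood, of globin copies, of the endothelial share and of the GC and length trend were chosen only after results were seen, and the last of these on vessel genes when the correction's effect on the count of calls was known. The splits were planned.

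Genes that keep the daily rhythm stood higher at altitude in mice given IOX2, with 10 higher and 5 lower. This call is from preset camera (adjusted p = 0.000527, and adjusted p = 0.464 with an estimated correlation). With vehicle the clock list was not called (median 0.03, preset camera adjusted p = 0.124, and adjusted p = 0.764 with an estimated correlation), and its scores were highest in HI1 (0.40), while HI3 (-0.01) was below MI3 (0.01). Averaged over treatment, clock genes had a median log2 change of 0.26 (preset camera adjusted p = 0.000963, and adjusted p = 0.478 with an estimated correlation). The repressor genes Ciart (1.12), Per1 (0.61), Per2 (0.67) and Bhlhe41 (0.34) led the 6 higher and 2 lower members that passed when adjusted over the list alone, against 0 over all genes. Dendritic-cell genes stood lower (median -1.33, preset camera adjusted p = 0.000765, and adjusted p = 0.478 with an estimated correlation). Foxp3, the factor of regulatory T cells, had a log2 change of -1.55 (adjusted p = 0.138) and the inhibitory receptor gene Tigit of 0.66 (adjusted p = 0.122); both passed when adjusted over their list alone. Chil3, a lectin gene of myeloid cells chosen after its values were seen, had a log2 change of 4.32 (SE 0.95, adjusted p = 0.0702) and did not pass. The macrophage list went the other way, with 11 of 15 members lower with vehicle and 13 of 15 with IOX2, and was called in neither.

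Some tumour pieces differed in what else they held. MI1 had the highest scores for B and plasma cells (5.54), T cells (1.35), dendritic cells (1.54), neutrophil precursors (1.95) and skeletal muscle (2.22). Adipocyte scores were 2.22 in HC1, 1.57 in HC2 and 1.47 in HI2. Keratinocyte scores were 1.37 in HC3 and 1.29 in HI1. HIF target scores were -0.45 in HC1 and 0.49 in HI1.

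Red-cell genes were higher with IOX2. Uneven splitting of reads between near-identical globin copies was argued against, since every copy was higher in the IOX2 average. The summed alpha-globin counts had a log2 change of 2.06 (SE 0.20) and the summed beta-globin counts of 1.95 (SE 0.22). These sums had to rise once every copy did, so they add no separate support. A GC and length trend was argued against as the whole cause, since the erythroid median was 2.099 after the correction and 2.03 before. Whole blood in the tumours and a change within the red-cell lineage cannot be told apart. The platelet score changed by 0.33 (SE 0.18) and the erythroid score by 1.68 (SE 0.21), a difference of 1.35 (SE 0.20). That difference decides nothing, since only 2 platelet genes reached 1 CPM in MC, under a minimum of 3 that was set after the result was seen. The platelet gene Ppbp passed the filter but not the limit of 1 CPM. Its means were higher with IOX2, at 0.329 CPM in MC against 0.716 in MI and 0.390 in HC against 0.663 in HI. A candidate explanation is that IOX2, and altitude itself, brought more young red cells into the blood, as HIF activation does through erythropoietin, which stays untested in these tumours.

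Some vessel genes were lower at altitude, while the 18 endothelial markers were called in the average only by preset camera (adjusted p = 0.000121, and adjusted p = 0.501 with an estimated correlation) and Vwf had a log2 change of 0.78. For the 8 called vessel genes (Vash1, Cd93, Mcam, Dll4, Hey1, Bcl6b, Pcdh12 and Scarf1, chosen after their values were seen), a GC and length trend was argued against as the whole cause, since their median log2 change was -0.62 after the correction and -0.65 before, with 8 of 8 past the threshold. With vehicle, the score of the 18 markers, a list fixed beforehand, changed by 0.06 (SE 0.13), with a median log2 change of -0.02. The score of the vessel genes changed by -0.57 (SE 0.07). The markers thus argue against a loss of endothelial cells as large as that fall, but a smaller loss stays open. The difference of 0.63 (SE 0.12) decides nothing by itself, since the vessel genes were picked for falling in an average that includes these mice. With IOX2, fewer endothelial cells and lower levels per cell cannot be told apart, since markers (-0.46, SE 0.13) and vessel genes (-0.81, SE 0.07) were both lower, with a difference of 0.35 (SE 0.12). No change of regulation within endothelium was tested.

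Whether other groupings of the mice give as many called genes was counted on other splits. For the altitude average, 1 of 100 drawn splits, the real one, gave 76 genes or more, a share under 0.05. The highest other gave 71, the split that exchanges only MI1 and HI3, and 97 gave no gene. The count was 2 without MC2 and 2 without MC3, so the splits do not make the single calls certain. For the IOX2 average, 1 of 100, the real one, gave 6 or more, and the highest other gave 0. For the comparisons of 2 groups, the 10 splits are too few for a share under 0.05: for IOX2 at ambient altitude 1 of 10 gave 4 or more (real 4, highest other 0), and for the others 10 of 10 gave 0 or more (real 0, highest other 0), where edgeR found 1829, 2321 and 740 genes at an unadjusted p under 0.05 and DESeq2 called 314, 381 and 22.

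Across genes, the altitude effect with vehicle and that with IOX2 correlated at 0.292, and 5 of 100 splits, the real one included, gave as large a correlation (highest other 0.541). The IOX2 effects at the different altitudes correlated at -0.161, with 78 of 100 as large (highest other 0.440).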
